A study of Rattus norvegicus with 16 samples.

How the data were processed

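Total RNA from the arcuate nucleus of 16 rats was amplified, labelled with Cy3 or Cy5 and hybridised to Agilent arrays, per the labels' protocols. Images were read with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes; the background step and the rule that left spots without a value are not given in the sources used here. The deposited values are on a log2 scale, as the values themselves show: every sample's median over its own listed spots was 0, and 2 to the power of each value times 1 constant per sample gave whole numbers within 0.01 for 100% of listed spots. The signals quoted were recovered that way. Because each sample was centred on its own listed spots, a sample that lists fewer dim spots has its remaining values set lower.

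Groups, sex and dye came from the labels. The free-text descriptions of male saline 4 and female saline 4 name another group than their titles, source names and sex fields, which were followed. The table identifies spots by number only, and those numbers were not linked to genes here. The planned rules of 1 probe per gene, the gene list tests, the cell type markers, the check of sex-linked genes and the named genes could therefore not be applied. The unit of every test is the spot, and spots of one probe or gene were not merged. In place of the named genes, the 2 spots with the highest rise and the 2 with the deepest fall over both sexes among those past the threshold are named, with the spot that passed the test between sexes.

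The 27294 spots listed in all samples were tested with limma 3.58.1 (statmod 1.5.0, R 4.3.3), with 4 group means, dye as a covariate, and array as a random block (duplicateCorrelation; estimated correlation 0.012 as deposited and 0.175 recentred). Contrasts were betamethasone less saline in males, in females and over both sexes, the difference of those effects, and female less male after each treatment. Spots with a Benjamini-Hochberg adjusted p under 0.05 were counted. This design was fixed before the data were examined. Centring on each sample's median had also been planned, but the deposited medians were already 0, so it changes nothing; centring on the median of the spots listed in all samples ("recentred") was chosen after seeing the data and is given beside the deposited values for the count of each comparison and each named spot's change over both sexes. Brightness was compared with exact permutation tests (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, Python 3.11.15), and plots were drawn with matplotlib 3.10.9.

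The fit was tested on simulated data with 50 spots at each of 4 fold sizes among 27294 spots: for both sexes it found 64% of spots changed 1.5-fold, 98% changed 2-fold and 100% changed 3-fold, with 11 false calls. The changed spots were drawn at random, so these shares do not describe the most variable spots. Noise was drawn independently for each spot. Alternatives covered normalisation, a filter on dim spots, the array block, dye, the replicate number, the samples in the fit, eBayes settings, thresholds and leaving out samples. Where the replicate number was a block, it took the place of both the array block and the dye term. Fits that leave out 1 sample, and those on other splits of the samples, kept the array correlation estimated from all samples.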

Results

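The arcuate nucleus of the hypothalamus, which houses neurons that govern feeding, growth hormone release and reproduction, was profiled in Sprague-Dawley rats on postnatal day 14. Their dams had received 2 injections of betamethasone, a synthetic glucocorticoid that crosses the placenta, at 0.4 mg/kg on gestation day 15, or saline. The series crossed sex with prenatal treatment and held 16 animals, 4 in each of 4 groups: male saline, male betamethasone, female saline and female betamethasone. Each array carried 2 animals of 1 group, one labelled with Cy3 and the other with Cy5, so that 8 arrays held all samples and each group had 2 samples in each dye. The treatment was given to dams, and the litter of each animal is not given in the sources used here. The p-values measure the spread between animals, and litter mates in a group would make them too small. Arrays lie within groups, so differences between arrays would do the same where the array block does not take them up. As deposited the block changed little: males, females and both sexes had 1938, 3544 and 7281 spots with it and 2052, 3691 and 7416 without. Averaging the samples of an array gave 0, 1306 and 5501.

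Values were listed for 28858 to 33104 of 44254 spots in Cy3 samples and for 37927 to 42833 in Cy5 samples, and 27294 spots were listed in all 16 samples. The number of arrays limits the precision. In Cy3, samples of betamethasone animals listed fewer spots, 29312 ± 534 (SD, n = 4) against 32662 ± 312 after saline, with no overlap (exact two-sided permutation test, p = 0.0286, the smallest that 4 against 4 allows; Benjamini-Hochberg adjusted p = 0.0571 over 4 tests). Their median Cy3 signal over the spots listed in all samples was 1544 ± 88.1, against 2820 ± 443 after saline (exact permutation p = 0.0286, adjusted p = 0.0571). In Cy5 the numbers of listed spots were 42684 ± 157 and 41565 ± 2425 (exact permutation p = 0.771), and the median signals were 820 ± 48.4 after betamethasone and 689 ± 43.6 after saline (exact permutation p = 0.0571, adjusted p = 0.0762).

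**Figure D1:**
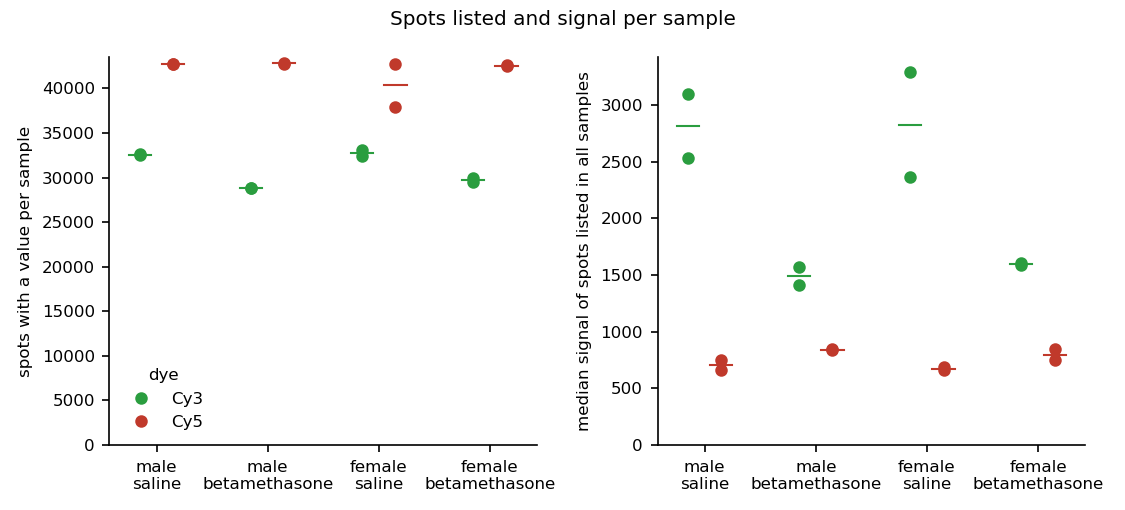
Spots with a value (left) and median signal of the spots listed in all samples (right, arbitrary scanner units), one point per sample, by group and dye, with bars at the mean of the 2 samples. The Cy3 samples of betamethasone animals lie at 28858 to 29948 listed spots, below the 32394 to 33104 of the Cy3 samples of saline animals.

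The first comparison asked which transcripts differed after prenatal betamethasone over both sexes. As deposited, 7281 of 27294 spots passed (limma, adjusted p under 0.05), 401 higher and 6880 lower, so that 94.5% were lower. The median log2 change over all spots was -0.19, and it lay in Cy3 alone: -0.42 in males and -0.35 in females, against 0.01 and 0.02 in Cy5. With every sample centred on the spots listed in all samples, a choice made after the data were seen, 1521 spots passed, 762 higher and 759 lower (49.9% lower), of which 1108 passed in the same direction as deposited; the recentred count was 501 without female betamethasone 4 and 667 with the samples of an array averaged. This balance differed between dyes: recentred, the Cy5 samples alone gave 420 higher and 1091 lower spots, and the Cy3 samples alone 58 higher and 8 lower. The changes were mostly modest: the median size among those 1521 spots was 0.54 on the log2 scale, with 69 spots over 2-fold higher and 20 over 2-fold lower.

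Among the spots that rose most as deposited were spot 14810, by 1.96 ± 0.41 on the log2 scale (SE; limma adjusted p = 0.00184), and spot 10482, by 1.55 ± 0.36 (adjusted p = 0.00422). Recentred, these changes were 2.17 ± 0.46 (adjusted p = 0.016) and 1.76 ± 0.43 (adjusted p = 0.0276). Spot 10482 rose by 2.01 ± 0.51 in females (limma adjusted p = 0.0164, 0.0806 recentred). Its change in males, 1.08 ± 0.51, did not pass (limma adjusted p = 0.201, 0.475 recentred). Its recentred, dye-adjusted log2 level was -4.41 in male saline 1 and 0.12 in male betamethasone 1, and -2.38 to -1.68 in the other males. The recentred, dye-adjusted log2 level of spot 14810 was -0.28 ± 0.77 in female saline and 2.42 ± 0.67 in female betamethasone animals (SD, n = 4), and it ranged from -2.18 to 0.12 in male saline and from -1.31 to 1.87 in male betamethasone animals. The spots that fell most were spot 6367, by -2.25 ± 0.34 (adjusted p = 0.000197), and spot 2710, by -2.23 ± 0.34 (adjusted p = 0.000196); recentred, the changes were -2.03 ± 0.41 and -2.02 ± 0.41 (adjusted p = 0.0138 for both). Spot 6367 went from 3.23 ± 0.89 to 1.42 ± 0.83 in males and from 4.89 ± 1.13 to 2.64 ± 0.57 in females (SD, n = 4). Spot 2710 ran close to it, from 3.07 to 1.29 in males and from 4.80 to 2.54 in females, so these may not be separate transcripts. The transcripts behind these spot numbers were not identified here.

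**Figure D2:**
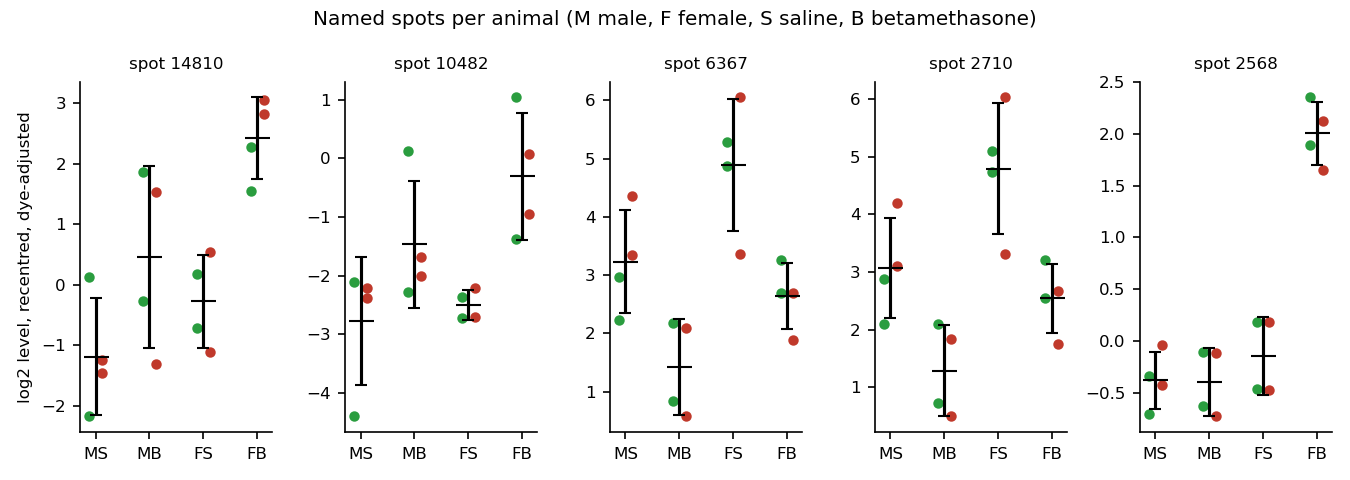
Recentred, dye-adjusted log2 level (vertical axis, a separate scale in each panel) of 5 spots in each animal, by group on the horizontal axis; green points are Cy3 samples, red points are Cy5 samples, and black bars give the mean and SD of 4 animals. Spot 2568 lies between 1.65 and 2.35 in female betamethasone animals and no higher than 0.18 in any other animal.

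In males alone, 1938 spots passed as deposited, 45 higher and 1893 lower. Recentred, 0 spots passed with limma, and 2822 had an unadjusted p under 0.05; the quantile-normalised values also gave 0. On data simulated for the male comparison, limma found 74% of spots changed 2-fold and 22% of spots changed 1.5-fold, at randomly drawn spots, with 14 false calls. The simulated spots varied independently, whereas some real spots varied together, so these shares are a rough guide to the count of 0. Those shares do not hold for spots that vary more: recentred, spot 6367 changed by -1.81 ± 0.58 in males and spot 14810 by 1.65 ± 0.65, and neither passed (limma adjusted p = 0.35 and 0.415). As deposited, the count was 402 without male saline 4 and 0 with the samples of an array averaged.

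In females, 3544 spots passed as deposited, 317 higher and 3227 lower. Recentred, 242 passed, 145 higher and 97 lower, with 77 over 2-fold higher, 23 over 2-fold lower, and a median size of 0.92 on the log2 scale; 229 of them passed in the same direction as deposited. Spot 14810 rose by 2.51 ± 0.58 in females (limma adjusted p = 0.0102; 2.70 ± 0.65 and adjusted p = 0.0559 recentred), against 1.41 ± 0.58 in males (adjusted p = 0.138; 1.65 ± 0.65 and adjusted p = 0.415 recentred). The difference between the female and male changes of spot 14810 was 1.09 ± 0.82 as deposited and did not pass (limma adjusted p = 0.9998). The recentred count rested on few animals: it was 9 without female betamethasone 4 and 844 without female saline 3. With the samples of an array averaged, 1306 spots passed as deposited and 16 recentred, and recentred counts by dye were 0 in Cy3 and 514 in Cy5 samples alone, the latter 20 without female saline 4.

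The male and female changes were compared next. Across spots, which are not independent replicates, the male and female changes correlated with a Pearson r of 0.54 and a Spearman rho of 0.49. Between animals of different sex, dye and array, r was 0.34 for male Cy3 with female Cy5 changes and 0.20 for female Cy3 with male Cy5 changes. Exchanging treatment labels within sex and dye gave absolute values of up to 0.204 for the first pair and 0.179 for the second. The value of 0.20 lay close to these, so it is not taken to stand apart.

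The difference between the female and male responses was tested directly, and 1 spot passed as deposited and recentred, spot 2568, named because it alone passed and so chosen after its values were seen. Recentred, it stood at 2.00 ± 0.30 in female betamethasone, -0.15 ± 0.38 in female saline, -0.40 ± 0.33 in male betamethasone and -0.38 ± 0.28 in male saline animals (log2, SD, n = 4). Its female change exceeded its male change by 2.21 ± 0.29 (SE; limma adjusted p = 0.00454), or by 2.17 ± 0.31 recentred (adjusted p = 0.0496). The difference stayed between 1.90 and 2.33 in all settings tried, but the call was lost with the samples of an array averaged (limma adjusted p = 0.743, and 0.9999 recentred), with quantile normalisation (0.0629), without a dye covariate (0.178), with the replicate number as a block on recentred values (0.107), within either dye, and in 14 of 16 recentred fits that left out 1 sample. Unadjusted p-values under 0.05 numbered 1247 as deposited and 1278 recentred. The counts of 0 in males and 242 in females after recentring therefore do not show that the sexes responded differently.

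Between the sexes after saline, 0 spots passed with limma as deposited and recentred, with 2475 and 2058 at an unadjusted p under 0.05. Only spots listed in all samples were tested, so transcripts listed only in males or only in females could not appear. As deposited, 22 passed without female saline 1 and 23 without female saline 2, and 8 (15 recentred) with the replicate number as a block. After betamethasone, 328 spots differed as deposited, 230 higher in females and 98 higher in males, and 137 recentred, 72 higher in females and 65 higher in males. The median size among the recentred calls was 1.20 on the log2 scale, a value raised by the threshold they had to pass. With only the groups compared the count was 34, with the samples of an array averaged 131 (84 recentred), recentred within each dye 0, and recentred without female betamethasone 4 it was 11. A split of these animals by dye instead of sex, which takes in any difference of the treatment effect between dyes, gave 2431 spots as deposited and 134 recentred. Taken over the saline animals, which entered the choice of those 137 spots only through the shared spread and dye term, the mean of the female-higher spots less that of the male-higher spots was 0.256 to 1.15 in the 4 females and -0.877 to -0.408 in the 4 males. Male saline 4 (-0.408) and female saline 4 (0.583), whose free-text descriptions name another group, stood with the sex of their titles.

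**Figure D3:**
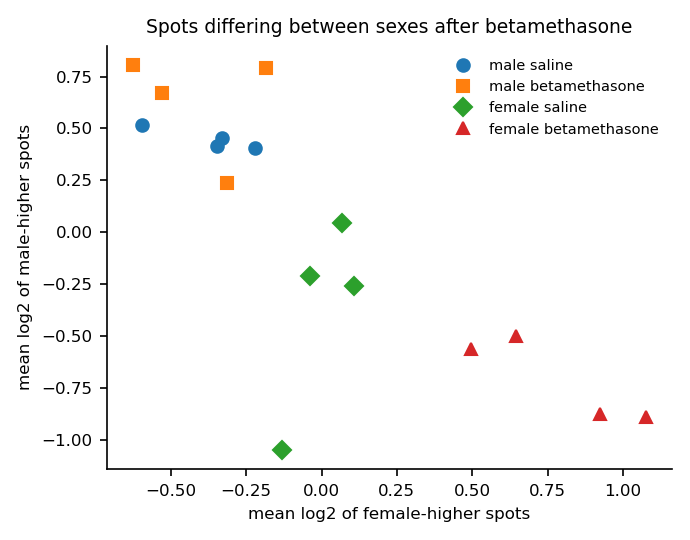
Mean dye-adjusted log2 level of the 72 female-higher (horizontal axis) and 65 male-higher spots (vertical axis), one point per animal, recentred values. The spots were chosen for differing between the betamethasone groups, which therefore lie apart by construction; the saline males lie at -0.60 to -0.22 and the saline females at -0.13 to 0.11 on the horizontal axis.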

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

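The tests of list length, of variation within groups, without female saline 4 and with sexes exchanged within treatment were written down before they were run, that of list length after recentring had already removed the shift. The other splits of the samples, the dimming tests, the remaining Cy5 tests and the choice of recentring came after the results were seen.

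Female saline 4 listed 37927 spots, where the other Cy5 samples listed 42504 to 42833, and the SD of its values, 2.12, was the highest of the 8 Cy5 samples; its residual SD was 0.353, against 0.159 to 0.270 in the others. Spot 10482 stood at -4.41 in male saline 1, apart from the rest of its group. These were 3 of 28 sets of samples examined, and chance sets about 1 in 20 apart. Spot 2568 alone passed the test of a difference in response between sexes, by 2.21 on the log2 scale. In Cy3, 1215 spots were listed in all 4 saline and in no betamethasone sample, and 1 the other way round; they entered no comparison.

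The calls over both sexes were mostly lower as deposited, and when every Cy3 sample was listed down to its 28858 brightest spots and centred on their median, the Cy3 shift between treatments went from -0.39 to -0.0023, leaving 0.607%; this decides nothing, because those lists are nearly the spots listed in all samples and centring on them fixes the outcome, so shorter lists stay open for the Cy3 samples. A lower level of most transcripts in both dyes is argued against by the Cy5 signals before centring, of which 26.0% at most were lower in either sex, though labelling and scanning also set those signals. In the Cy5 samples alone, shorter lists are argued against, since 1091 of 1511 recentred calls (72.2%) were lower. Leaving out female saline 4 brought that share to 59.97%, just under the limit set beforehand for attributing the excess to it. The number of lower calls did not fall, however, and that fit leaves 1 female saline sample. The part of female saline 4 in the excess therefore stays open.

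For the 1215 spots, a dimmer Cy3 channel may be the source, as the Cy3 signal ratio was 0.548. The first form of the test, with signals dimmed in all 4 saline samples to under the lowest listed signal (69.5), covered 21.2% of them (257 spots). A looser form, chosen after that value was seen, used the mean signal and the 1st percentile of listed signals (90.0) and covered 85.8%, against 0.537% of 27361 always listed spots. The forms disagree, so this stays open. Less RNA of these transcripts is argued against by Cy5, where their median change was 0.246 (interquartile range 0.110 to 0.384, 1028 spots) against 0.0662 for all common spots, though their median Cy5 signal of 209, against a 1st percentile of 102, leaves little room above background.

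The 137 spots that differed between sexes after betamethasone varied together within groups. The mean pairwise correlation of deviations from group and dye means was 0.418 for female-higher and 0.538 for male-higher spots. Both lay above the highest of 1000 level-matched random sets (0.128 and 0.050), which argues against a distortion shared by all spots of like level. The random sets were matched neither for spread nor for having been called in these data, so they bear on level alone. Over saline samples the means were 0.385 and 0.580. RNA from neighbouring cells taken in varying share at dissection, spots of one gene, and regulation shared by these spots cannot be told apart, because no spot was linked to a marker here. The hypothesis of a common source may be followed up once spots are named.

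Other splits of the same samples were counted with the real one included. Over both sexes, 1 of 100 drawn splits gave as many spots as the real 7281 as deposited (highest other 2). Recentred it was also 1 of 100 (1521, highest other 0). With animals as units this excludes chance recentred, but the real split was the only one drawn that keeps arrays whole. For females it was 1 of 35 as deposited (3544 against 11) and recentred (242 against 2). With animals as units this excludes chance recentred, but only 3 of the 35 splits keep arrays whole, the real one among them. For males as deposited it was 1 of 35 (1938 against 21). As deposited, the Cy3 shift sets the real split apart each time, so those counts do not exclude chance for single spots. Males recentred decide nothing, because every split gives at least the real 0 (35 of 35, highest other 101). For the difference in response between sexes, exchanging treatment (4 of 100 splits with at least the real 1 spot, highest other 379; recentred 2 of 100, highest other 6) decides nothing, because the treatment effect itself then enters the difference. With sexes exchanged within treatment, 5 of 100 splits gave at least 1 spot as deposited (highest other 14) and 4 of 100 recentred (highest other 1, a tie with the real count), so chance is not taken as excluded. Between sexes after betamethasone, 2 of 35 splits gave as many as 328, the other being the split of Cy3 from Cy5 with 2431. A difference of the treatment effect between dyes, such as the Cy3 shift, enters that split, so it does not measure chance. Chance is not taken as excluded as deposited. Recentred, 1 of 35 splits gave as many as the real 137, with the dye split at 134. Within dye, the recentred count was 0 in Cy3 and 0 in Cy5. After saline the real count was 0, so 35 of 35 splits gave at least as many by construction, which decides nothing. The dye split, which takes in the same difference between dyes, gave 3420 as deposited and 214 recentred. These splits take animals as units; if arrays are the units, too few splits exist to exclude chance.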

How the results depend on the processing

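Centring on the spots listed in all samples, every setting that adds to it, and the fits within a dye were chosen after seeing the data; the other settings were planned. Counts below run in the order males, females, both sexes, difference between sexes, sexes after saline, sexes after betamethasone. Unless stated, only counts that moved by over 1.5 times from the main count as deposited are given, also for recentred settings. A count left out of a recentred setting can therefore still differ from the recentred count. The cause was not tested unless stated. Directions of the 5 named spots never reversed: past the threshold were spot 14810 in 50 of 51 settings, spot 10482 in 46 of 50, spots 6367 and 2710 in 48 of 51 each, and spot 2568 in 25 of 51. Recentred counts were 0, 242 and 1521, with 137 for sexes after betamethasone. Quantile normalisation gave 0, 473, 2521 and, for the difference, 0. With the samples of an array averaged, which leaves fewer samples, counts were 0 for males, 1306 for females, 0 for the difference and 131 for sexes after betamethasone; recentred they were 0, 16, 667, 0 and 84. With no array block, recentred counts were 0, 1301 and 3210. Sexes after betamethasone then had 343, near the deposited 328 but above the recentred 137. Without a dye covariate the difference between sexes had 0. With only the groups compared, females had 2003 and sexes after betamethasone 34. With trend and robust set, sexes after saline had 1. An adjusted p under 0.10 gave 3597, 5709, 1 (sexes after saline) and 652. An unadjusted p with 1.5-fold gave 1730 for both sexes, 840, 618 and 1386. Without male saline 4 and female saline 4, males had 966 and females 2045; recentred, 0, 13, 344, 0 for the difference and 74 for sexes after betamethasone. Cy3 samples alone gave 61 for females, 13819 for both sexes, 0 and 14, and recentred 0, 0, 66, 0 and 0; Cy5 samples alone gave 0, 592, 1640, 3, 6 and 0, and recentred 0, 514, 1511, 3, 7 and 0. Cy5 samples without female saline 4, which leaves 1 female saline sample assumed to vary like the other groups, gave 1, 3, 1484, 6, 8 and 0, and recentred 3, 20, 1931, 6, 10 and 0. Recentred with spots listed in 3 or more samples of each group, counts were 0, 58, 1479, 0 and, for sexes after betamethasone, 103.

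No label pairs animals by replicate number, and their deviations gave no clear sign of it. The 24 same-numbered pairs correlated at -0.496 to 0.332, 1 of them over 0.1, and 2 of 16 samples correlated best with their own number. Same-numbered samples share a dye, and removing group and dye means lowers their correlations, so a pairing is not excluded. With the replicate number as a block in place of the array block and the dye term, males had 1272 and sexes after saline 8. Recentred, that fit gave 0, 775, 2538, 0 and, for sexes after saline, 15, with 267 for sexes after betamethasone. Dropping the array block alone gave 1301 in females and 3210 over both sexes recentred. The rise in those 2 counts is therefore not put down to the replicate number.

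Leaving out each sample in turn gave, as deposited, 402 (without male saline 4) to 2638 spots in males, 1470 (without female betamethasone 4) to 4040 in females, 5608 to 8744 over both sexes, 1 to 3 (without female saline 3) for the difference, 0 to 23 (without female saline 2) after saline and 117 (without female betamethasone 4) to 519 (without male betamethasone 2) after betamethasone. Recentred, the ranges were 0 to 0, 9 to 844, 501 to 2029, 0 to 1, 0 to 1 and 11 to 221, the lowest in females, over both sexes and after betamethasone each without female betamethasone 4 and the highest each without female saline 3. Not run were the mean of a gene's probes, 1 probe per gene and gene lists, which need gene names, and a pseudocount, since values are on a log scale. Signal over background limits the dim spots, many of which have no value in Cy3.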
